A study of Mus musculus with 2 samples.

How the data were processed

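EP300 ChIP-seq was measured in whole lung of newborn mice (strain B6NCrl, postnatal day 0) in 2 libraries, which form 1 group. Per the labels they are biological replicates 1 and 2, with the same donor and biosample record, and the sex of the tissue was not collected. The labels also name a possible control experiment, not analysed here.

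Per the notes deposited with the libraries, the authors aligned reads to mm10, called peaks on each library and on both pooled, and made conservative and optimal sets of reproducible peaks from these lists by the irreproducible discovery rate (IDR). Each list was also derived from 1 further file whose content the notes do not name. The aligner, the peak caller and the IDR version were not given in the sources used here. The signal values are those deposited by the authors for each peak, with no scaling stated, and the optimal and conservative sets carry the signal of the pooled list. The score values deposited by the authors with these sets are integers from the IDR step, from 537 to 1000, with 22034 optimal peaks at 1000, and were not used. The q field held values below 0 and was not used. Signal values served to rank, sum, describe and filter peaks within a list. They were also used to compare shared peaks between the libraries, and in the tests of the X chromosome and of peaks of like signal. The lists gave no read counts, so depth and the precision it allows could not be stated.

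The fixed choices were made before the data were examined. The per-library and pooled lists held 300000 peaks each, the conservative set 42473 and the optimal set 43988, the main set. Peaks on other sequences than the 21 chromosomes (16 of the optimal set) were left out of the promoter, gene and sequence work, for want of annotation in use, which left 43972. Genes and TSSs were those of GENCODE vM21 on GRCm38.p6, with 21827 protein-coding genes.

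Replicate overlap was the percent of the strongest 43988 peaks of each library with a summit within 100 bp in the other, against random placement of one library's summits. A promoter peak had its summit within 1 kb of a protein-coding TSS, and shares were compared with pooled peaks that overlapped no optimal peak by a two-sided Fisher's exact test. Single libraries were represented by their strongest 43988 peaks.

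Gene lists (28, with 606 symbols, of which 605 were matched, 1 through an older name) were fixed beforehand, and 27 genes stood in more than 1 list. Peaks were assigned to the nearest protein-coding TSS within 100 kb, which is not a measured link. The mean number of peaks per gene was compared with 100000 random lists matched on the decile of gene territory, by a two-sided permutation test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Genes were named by a fixed rule: the 4 members with most peaks in a list that passed the test, the 2 with most in any other list, the nearest genes of the 10 strongest peaks, and the genes in or nearest to the 10 highest clusters. Ties between members went to the gene with the strongest assigned peak, then by alphabet. A member left unnamed may therefore have as many peaks as the last one named. Malat1, Neat1, Klf13 and Sdk2 fall outside the rule and were named after their values were seen.

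For 36 consensus sequences, matches on either strand in the central 100 bp were compared with the flanking window (300, 500 or 700 bp away) of nearest GC content by an exact sign test over peaks with a match in only one of them, adjusted over the sequences. Enrichment required an adjusted p under 0.05 and a ratio of at least 1.5. Where a window class had 3 or fewer matches, the counts or an exact interval are given. Clusters were runs of optimal peaks no further apart than a distance just over 12 kb, ranked by summed signal.

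The code was tested on simulated data. Lists simulated with 3-fold more peaks were called in 66 of 100 cases, with 2-fold in 13, with 1.5-fold in 3 and with none in 0. Lists of large territories with no change were called in 1 of 280. Each of 36 sequences was planted in 10% of windows and tested alone, without adjustment or the rule of a 1.5-fold ratio. All 36 then had a p under 0.05 and a ratio above 1. With nothing planted, 0 of 36 were called under the full rule. The planting rate was above most shares seen in the peaks, so sensitivity to rarer sequences was not measured.

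Alternatives covered the conservative set, the stronger 50% of the optimal set, each library alone, other distances, windows, promoter definitions and backgrounds. Merging overlapping peaks, leaving out optimal peaks of low pooled rank, leaving out genes of more than 1 list and splitting distal peaks by signal were added after the data had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and a random seed of 1.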

Results

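EP300 is a lysine acetyltransferase and transcriptional coactivator that is recruited to active enhancers and promoters by DNA-bound transcription factors. Its genomic positions were measured by chromatin immunoprecipitation with sequencing (ChIP-seq) in whole lung of B6NCrl mice on the day of birth (postnatal day 0). The data held 2 libraries of 1 group, so that no comparison between conditions was possible. The questions addressed were where EP300 was found in the newborn lung, near which genes, over which DNA sequences, and how far the 2 libraries shared these positions. The labels number the libraries as biological replicates 1 and 2 but give both the same donor and biosample record, so the spread between them may be technical. Each library had its own list of 300000 peaks, called separately, and a further list of 300000 peaks had been called on both libraries pooled. From these lists the authors had derived an optimal set of 43988 reproducible peaks and a conservative set of 42473. All values below refer to the optimal set on the mm10 build unless a library is named. The peak files gave no read counts, so the depth of each library was unknown, and intervals below cover only the counting of peaks, which are not replicates and are not independent of each other. The signal value of a peak is the authors' own and served mainly to rank and describe peaks within a list. It was also used to compare shared peaks between the libraries, and in the later tests of the X chromosome and of peaks of like signal.

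The strongest EP300 sites were shared by both libraries. The strongest peak of all, in an intron of Zbtb16, held rank 1 in each library, and 80 of the strongest 100 peaks of replicate 1 had a summit within 100 bp among the strongest 100 of replicate 2. Among the strongest 43988 peaks of each library, 65.7% of those of replicate 1 and 65.7% of those of replicate 2 had such a partner, against 0.350% with the summits of replicate 2 placed at random. The shared fraction was 78.9% among the strongest 1000 peaks, 76.9% among the strongest 10000, 49.5% among the strongest 100000 and 29.4% over all 300000, where random placement gave 2.37%. The 28884 peaks matched one to one had a median summit distance of 23.0 bp. After the median log2 ratio of 0.38 between the libraries was removed, 97.2% of the shared peaks were within 2-fold of each other. A stricter or looser definition moved the replicate overlap: 52.5% with summits within 50 bp and 75.7% with any overlap of 1 bp.

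**Figure D1:**
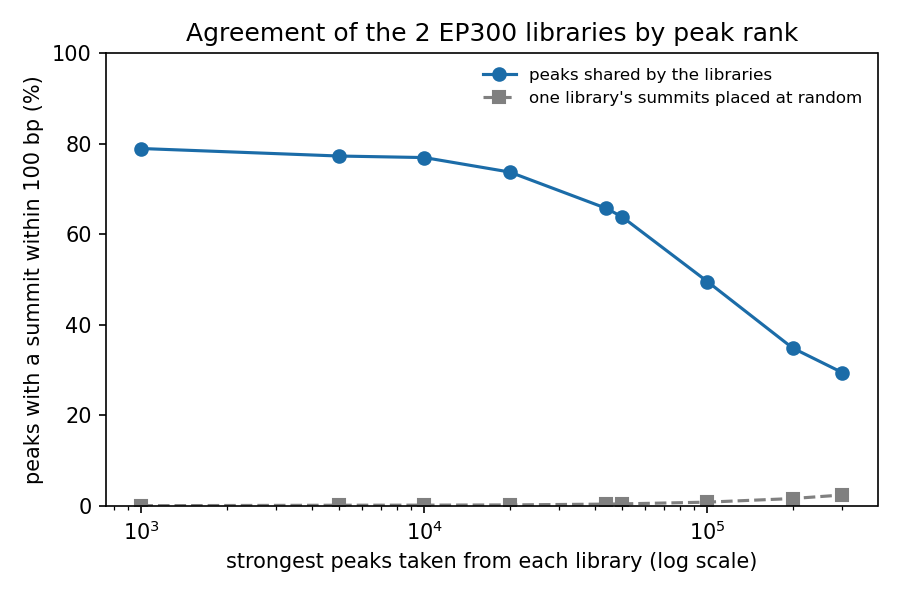
Percent of peaks with a summit within 100 bp in the other library (y axis) against the number of strongest peaks taken from each library (x axis, log scale), as the mean of both directions (circles) and with the summits of replicate 2 placed at random (squares). The shared percent was 78.9% among the strongest 1000 peaks and 29.4% over all 300000.

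EP300 peaks lay mostly far from genes' start sites, with promoters over-represented. Promoters, taken as the 1 kb on either side of a protein-coding transcription start site (TSS), held 5418 of 43972 optimal peaks on the chromosomes, or 12.3% (95% Wilson interval 12.02 to 12.63%). Introns held 42.6% and intergenic sequence 43.0%, while coding sequence held 0.641% and untranslated regions 1.42%. The median distance from a summit to the nearest TSS was 25.3 kb, 68.3% of peaks were over 10 kb away and 18.2% over 100 kb. At least 1 promoter peak was found at 4477 of 21827 protein-coding genes (20.5%). Promoter peaks had a median signal value of 44.8, against 49.1 for all others.

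The comparison set was the 249828 pooled peaks that overlapped no optimal peak, of which 5.73% lay in promoters, 2.15-fold less often than optimal peaks (two-sided Fisher's exact test, p at or below 1e-300, the smallest value printed here). Against random positions, of which 2.12% lay in promoters, the fold was 5.81. The comparison set had 44.7% in introns, 46.6% in intergenic sequence, 1.06% in coding sequence and 1.83% in untranslated regions. As the shares sum to the whole, a higher promoter share lowers the others, and no separate test of these classes is given. The strongest 43988 peaks of each library alone gave promoter shares of 12.8% for replicate 1 and 12.3% for replicate 2 (mean 12.53% ± 0.333, SD, n = 2), and the gap to the comparison set was larger than this spread. The promoter share was lower among strong peaks: 7.30% in the strongest 10% of the optimal set and 17.7% in the weakest 10%. Because neighbouring peaks overlap (20.01% of optimal peaks overlapped another), the exact p-values are too small, and the libraries' own values are the firmer guide.

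None of the 10 strongest peaks lay in a promoter. The first, with a signal value of 628, lay at chromosome 9, 48723454 to 48724019, in an intron of Zbtb16, a zinc finger transcription factor gene induced by glucocorticoids, 112 kb from the nearest TSS of that gene. The second (561) lay at chromosome 14, 101838505 to 101838865, in an intron of Lmo7, which encodes a LIM domain protein and is a marker of alveolar type 1 (AT1) cells, 1.96 kb from a TSS. The third (550) lay in an intron of Cblb, a ubiquitin ligase gene, at chromosome 16, 52094660 to 52094999. The fourth (530) was intergenic at chromosome 12, 85532577 to 85532891, and its nearest gene was the AP-1 gene Fos, 58.8 kb away. The eighth (512) lay at chromosome 3, 132940602 to 132940946, in an intron of Npnt, which encodes the matrix protein nephronectin. The ninth (507), at chromosome 7, 138919271 to 138919572, was intergenic and 9.93 kb from Bnip3, a hypoxia-responsive mitophagy gene. The remaining 4 had E030018B13Rik (527, in an intron of Klf13), Irf2bp2 (522), Slc44a3 (516) and Cdc42ep4 (503, in an intron of Sdk2) as nearest genes, with the host genes Klf13 and Sdk2 named after their values were seen. These 10 peaks ranked between 1 and 17 in replicate 1 and between 1 and 16 in replicate 2. The central 100 bp of 6 of the 10, nearest to Zbtb16, Cblb, E030018B13Rik, Irf2bp2, Npnt and Cdc42ep4, held a glucocorticoid response element.

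Genes of alveolar epithelium, endothelium and hormone or stress responses had more EP300 peaks than random genes from the same decile of surrounding sequence. Peaks were assigned to the nearest protein-coding TSS within 100 kb, which gave 1.65 ± 3.22 peaks per gene (SD over 21827 genes) and left 47.1% of genes with at least 1. The nearest gene is not necessarily the one a site acts on. Of 28 gene lists fixed before the data were examined, 13 had more peaks per gene than random lists matched on the size of the genes' territories, and 1 had fewer (two-sided permutation test, adjusted p under the Benjamini-Hochberg method over the 28 lists). In both libraries taken alone, the mean of each of these 13 lists lay above, and that of the other below, the mean of its random lists.

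Glucocorticoid-responsive genes had the highest density, 13.7 ± 8.48 peaks per gene (SD over 20 genes) against 2.12 in matched random lists, a ratio of 6.43 (permutation adjusted p = 9.33e-05, from the smallest p that 100000 random lists can give, 2e-05). All 20 genes had a peak and 17 had a promoter peak. Errfi1, a feedback inhibitor of EGF receptor signalling, had 31 peaks, Fkbp5, a co-chaperone of the glucocorticoid receptor, had 29, and Zbtb16 and the phosphatase gene Dusp1 had 21 each. The strongest peak of all, in an intron of Zbtb16 but 112 kb from its TSS, lay beyond 100 kb and was not counted among these 21. The mean was 13.7 in replicate 1 and 13.8 in replicate 2. Immediate early genes had 8.58 peaks per gene and a ratio of 4.37 (permutation adjusted p = 9.33e-05), led by Jun with 24, Klf6 with 22, Dusp1 with 21 and Fos with 18. Hypoxia-responsive genes had 5.10 ± 7.15 peaks per gene (SD over 20 genes, ratio 2.40, permutation adjusted p = 0.0123). There were 26 at Vegfa, the endothelial growth factor gene, 15 at Ddit4, 15 at Epas1 and 14 at Pfkfb3. Both Vegfa and Ddit4 also stand in other lists, and without genes of more than 1 list the hypoxia ratio was 1.63 (permutation adjusted p = 0.197), as it also missed the threshold with peaks within 10 kb only (adjusted p = 0.171) and by the share of genes with a peak (adjusted p = 0.102).

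Among lung cell types, AT1 markers had 10 ± 8.21 peaks per gene (SD over 20 genes, all with a peak) against 2.19 in random lists (ratio 4.57, permutation adjusted p = 9.33e-05). Vegfa had 26 peaks, the chloride channel gene Clic5 23, the membrane protein gene Emp2 21 and Lmo7 20, but Vegfa had 17 and Emp2 13 in replicate 2. Markers of alveolar type 2 (AT2) cells, which make surfactant, had 5.28 ± 4.36 peaks per gene (ratio 3.20, permutation adjusted p = 0.00305), and 16 of 18 had a peak. Sftpb, encoding surfactant protein B, had 18, the protease gene Ctsh 10, the ETS factor gene Etv5 9 and the cytokine gene Il33 8. Lung endothelial markers had 7.27 ± 4.85 peaks per gene (ratio 3.42, permutation adjusted p = 9.33e-05), and all 22 had a peak. The VEGF receptor gene Kdr had 15 peaks, and Egfl7, the ETS factor gene Erg and the endothelin receptor gene Ednrb had 14 each. Surfactant lipid synthesis genes were close to the threshold, with 3.90 peaks per gene (ratio 2.02, permutation adjusted p = 0.0416), and Scd2, with 14, led Lpcat1 and Chka with 7 each and Scd1 with 6. This last call was lost with either library alone (permutation adjusted p = 0.0520 for replicate 1 and 0.0523 for replicate 2), with the conservative set (0.0854) and under 4 further settings. The ratio was 1.93 with either library alone and 1.83 with the conservative set, and 1.68 at the lowest over all alternatives.

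Lists of 4 signalling groups, of matrix genes and of lung transcription factors also had more peaks, while the WNT list did not pass the test. Hippo and YAP target genes had 10.45 ± 11.97 peaks per gene (SD over 20 genes, ratio 4.35, permutation adjusted p = 9.33e-05). Dlc1 had 53, Tead1 32, Amotl2 14 and Tead4 11, so the mean rested in large part on single genes. TGF-beta and BMP genes had 7.93 (ratio 2.995, permutation adjusted p = 9.33e-05), with 25 at the inhibitor gene Smad7, 21 at the receptor gene Tgfbr2, 20 at Smad6 and 15 at Tgfbr3. FGF and receptor tyrosine kinase genes had 7.74 (ratio 2.70, permutation adjusted p = 0.00056), with 26 at Fgf1, 22 at Dusp6, 18 at Spry4 and 16 at Fgfr2. Extracellular matrix genes had 7.47 (ratio 2.63, permutation adjusted p = 0.00016), with 29 at Col4a1, 20 at Col4a2, and 19 each at Timp3 and Lamc1. The start sites of Col4a1 (11312826 on chromosome 8) and Col4a2 (11312805) adjoin, so their separate counts do not tell these genes apart. The strongest peak assigned to Col4a1 (11344566 to 11344818) lay within Col4a2. That assigned to Col4a2 (11234201 to 11234439) lay within Col4a1. Hedgehog and Notch genes had 5.64 (ratio 2.15, permutation adjusted p = 0.0133), with 19 at Hes1, 18 at Notch2, 14 at Boc and 13 at Ptch1. Boc had 9 peaks in replicate 1 and 6 in replicate 2, and Tead4 had 6 in replicate 2. Lung developmental transcription factors had 6.53 ± 7.36 (SD over 32 genes, ratio 1.94, permutation adjusted p = 0.00924), led by Foxp1 with 35, Nfib with 21, Foxa2 with 17 and Tbx2 with 14. This call was lost with the stronger 50% of peaks (permutation adjusted p = 0.0676) and with random lists also matched on promoter peaks (adjusted p = 0.0602).

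Neuronal markers were the list with fewer peaks, 0.750 per gene against 2.75 in random lists (ratio 0.272, permutation adjusted p = 0.0152). Gad2 and Neurod1 had 4 peaks each and Rbfox3 and Camk2a 2 each, but in replicate 2 and in the conservative set Camk2a had none and Neurod1 had 2. The call was lost with unmatched random lists (permutation adjusted p = 0.196) and with random lists also matched on promoter peaks (adjusted p = 0.130), among 3 settings. The other 14 lists did not pass the test. Of the resident lung cells among them, fibroblast and myofibroblast markers had a ratio of 1.57 (permutation adjusted p = 0.164, Npnt 16 and Eln 10 peaks), smooth muscle and pericyte markers 1.72 (0.143, Mylk 18 and Cox4i2 10), airway secretory and ciliated markers 1.41 (0.342, Scgb1a1 16 and Aldh1a1 9) and mesothelial markers 0.369 (0.202, Krt19 and Msln 3 each). Blood cell lists had ratios of 0.642 for macrophage and myeloid markers (0.395, Mpeg1 7 and Mrc1 3), 0.345 for lymphocyte markers (0.105, Ebf1 5, with 2 in replicate 2, and Tcf7 3) and 0.381 for erythroid markers (0.202, Tfrc 3 and Nfe2 2). WNT signalling had 1.26 (0.395, Ctnnb1 and Axin2 10 each). Lists of other organs gave 0.376 for hepatocyte (0.0989, Apoa1 5, with 9 in replicate 2, and Cps1 3, with 1 in replicate 1), 0.336 for cardiomyocyte (0.0523, Nkx2-5 and Kcnj2 2 each, Kcnj2 with 1 in replicate 2), 0.438 for skeletal muscle (0.143, Myog and Chrna1 3 each) and 0.889 for kidney and gut markers (0.888, Cubn 11 and Slc12a3 5). The control lists gave 1.94 for ribosomal protein genes (0.0610, Rpl5 and Rpl28 4 each, Rpl28 with 2 in either library) and 1.98 for housekeeping genes (0.0883, Actb 7 and Gapdh 4, with 11 and 2 in the conservative set), with promoter peaks at 23 of 30 and 11 of 20 genes. The control ratios were close to those of 3 lists that passed: lung developmental transcription factors (1.94), surfactant lipid synthesis genes (2.02) and Hedgehog and Notch genes (2.15). In simulated lists with 2-fold more peaks the test called 13 of 100, and with 3-fold more 66 of 100, so a list that did not pass is not shown to be unchanged.

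**Figure D2:**
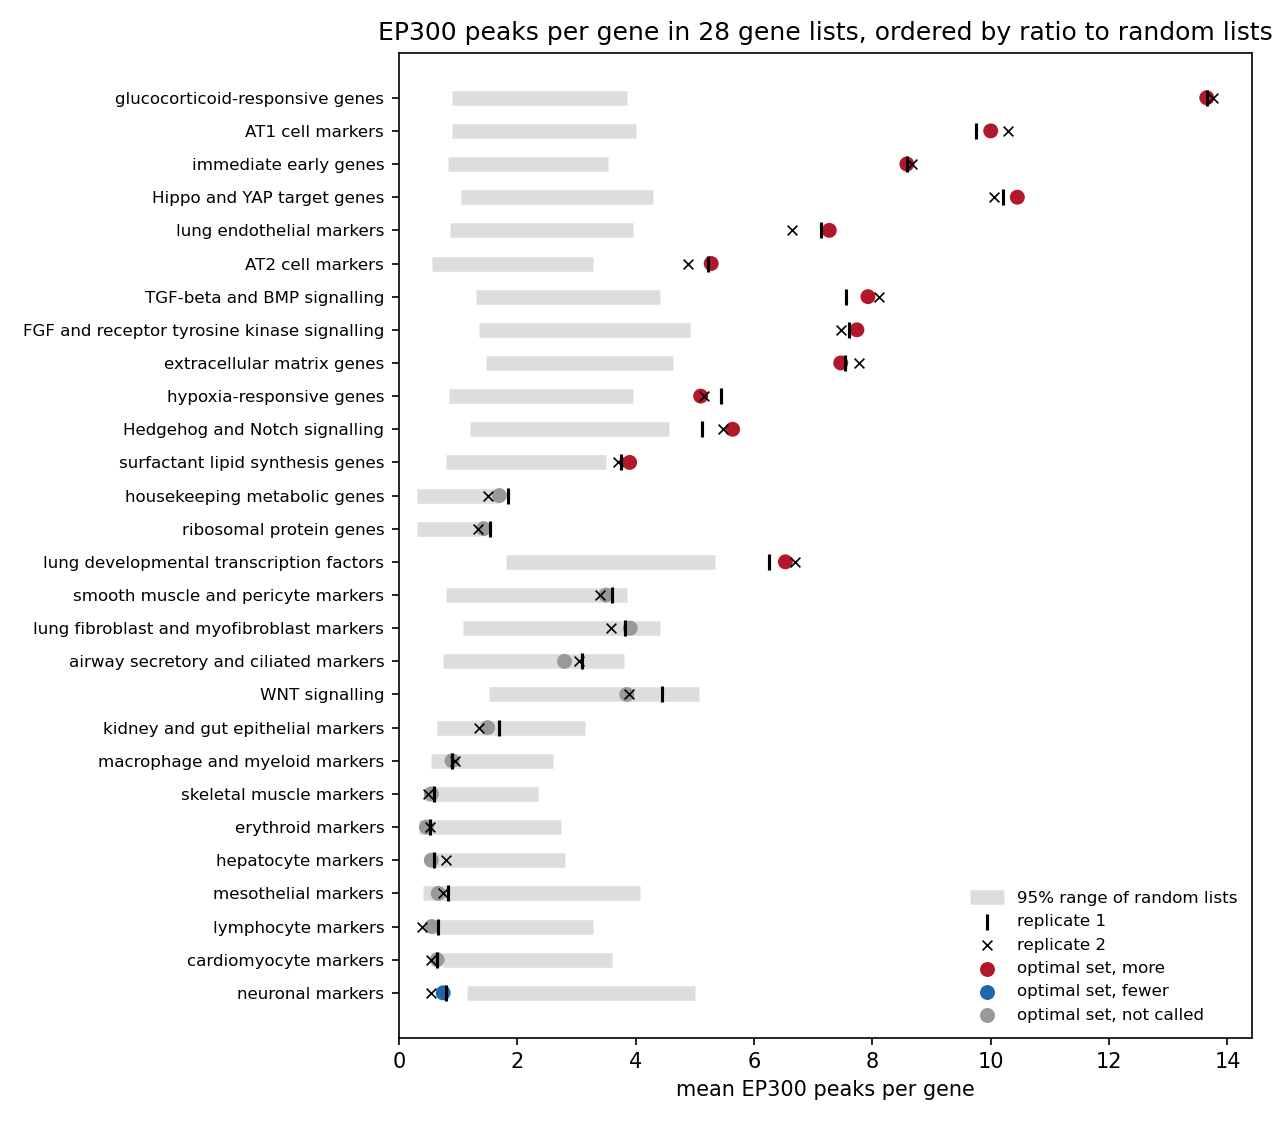
Mean number of EP300 peaks per gene (x axis) in 28 gene lists (rows, ordered by their ratio to random lists), with the optimal set as coloured circles (red more, blue fewer, grey not called), each library alone as black marks, and the 95% range of territory-matched random lists as grey bars. Glucocorticoid-responsive genes stood at 13.7 peaks per gene, with random lists between 0.900 and 3.85, and neuronal markers at 0.750, below their random range.

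The glucocorticoid response element had the highest ratio of centres to flanks of the sequences tested at EP300 summits. It occurred in the central 100 bp of 2.17% of peaks (95% Wilson interval 2.04 to 2.31%) and in 0.161% of flanking windows of like GC content, a ratio of 13.5 (95% exact interval 10.6 to 17.3; exact sign test, adjusted p = 2.83e-198). The libraries alone gave ratios of 12.4 and 10.7 (mean 11.5 ± 1.23, SD, n = 2). Of 36 consensus sequences fixed beforehand, 24 were enriched, having an adjusted p under 0.05 and a ratio of at least 1.5, and none was depleted.

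The enriched sequences included those of factors with known roles in lung and its vessels. The AP-1 site (TGASTCA) was in 5.94% of centres (ratio 3.27, exact adjusted p = 3.68e-229), the FOX site in 10.5% (2.63), the TEAD site, bound by the partners of YAP, in 8.24% (2.97) and the ERG-type ETS site in 7.29% (3.68). The NKX2 site was in 3.13% (2.14), the GATA site in 3.23% (2.33), the STAT site in 1.54% (5.09), the SOX site in 1.16% (2.22) and the MEF2 site in 0.516% (2.67). CEBP sites had ratios of 6.33 for the full consensus, with 95 centres, and 4.55 for the core, CREB 4.12, ETS 3.25, the ETS core 1.56 and KLF/SP 1.77. For NFI the short site had 1.64 and the full palindrome 4.50, from 18 centres and 4 flanks. E-boxes had 2.38 for the TCF21 type and 1.63 for CAGCTG, and GRHL 4.20 with 42 centres. CTCF, an insulator protein, had 6.45 with 200 centres. PU.1, with 15 centres and 2 flanks, had 7.5 (95% exact interval 1.74 to 67.6), and RFX, with 10 and 2, had 5.00 (1.07 to 46.9). RFX lost its call under 6 settings.

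The remaining 12 sequences were not called. Their ratios were 1.43 for the NKX2 core, 1.37 for NF-kB, 1.21 for RUNX and 1.13 for the CACGTG E-box, each past the adjusted p but under 1.5-fold, and 0.766 for TBX, which was depleted with the stronger 50% of peaks. SRF had 1.04, SMAD 1.11, HNF4 1.18 and NRF1 0.625 (5 centres, 8 flanks), none past the test, and HNF1 had 4.50 from 9 centres and 2 flanks (95% exact interval 0.931 to 42.8). The long p53 and REST consensuses had no match in centres or flanks, so no ratio is given. Some sites differed in share between promoter and distal centres: the KLF/SP site was in 11.8% of promoter centres and 5.55% of distal ones (Fisher's exact test, adjusted p = 6.37e-58), and the ETS site in 1.07% and 0.0856% (exact adjusted p = 1.22e-29). In the other direction, TEAD stood at 3.73% and 8.87% (exact adjusted p = 5.65e-44), FOX at 5.59% and 11.2% (9.98e-41) and the glucocorticoid response element at 0.572% and 2.40% (1.02e-22). Relative to their own flanks, KLF/SP had nearly the same ratio in promoter and distal peaks (1.75 and 1.78), while the ratios were 4.83 and 2.06 for ETS, 1.68 and 3.11 for TEAD, 1.99 and 2.69 for FOX and 5.17 and 14.2 for the glucocorticoid response element, with no test of these differences. With promoter peaks alone 15 sequences were enriched, in a set of 5418 peaks, and the calls of NKX2 (ratio 1.46), the short NFI site (1.17) and the full NFI site (2.25, exact adjusted p = 0.0850) were lost against shuffled sequence. With a 200 bp window the ETS core (1.32) and the CAGCTG E-box (1.48) were lost.

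**Figure D3:**
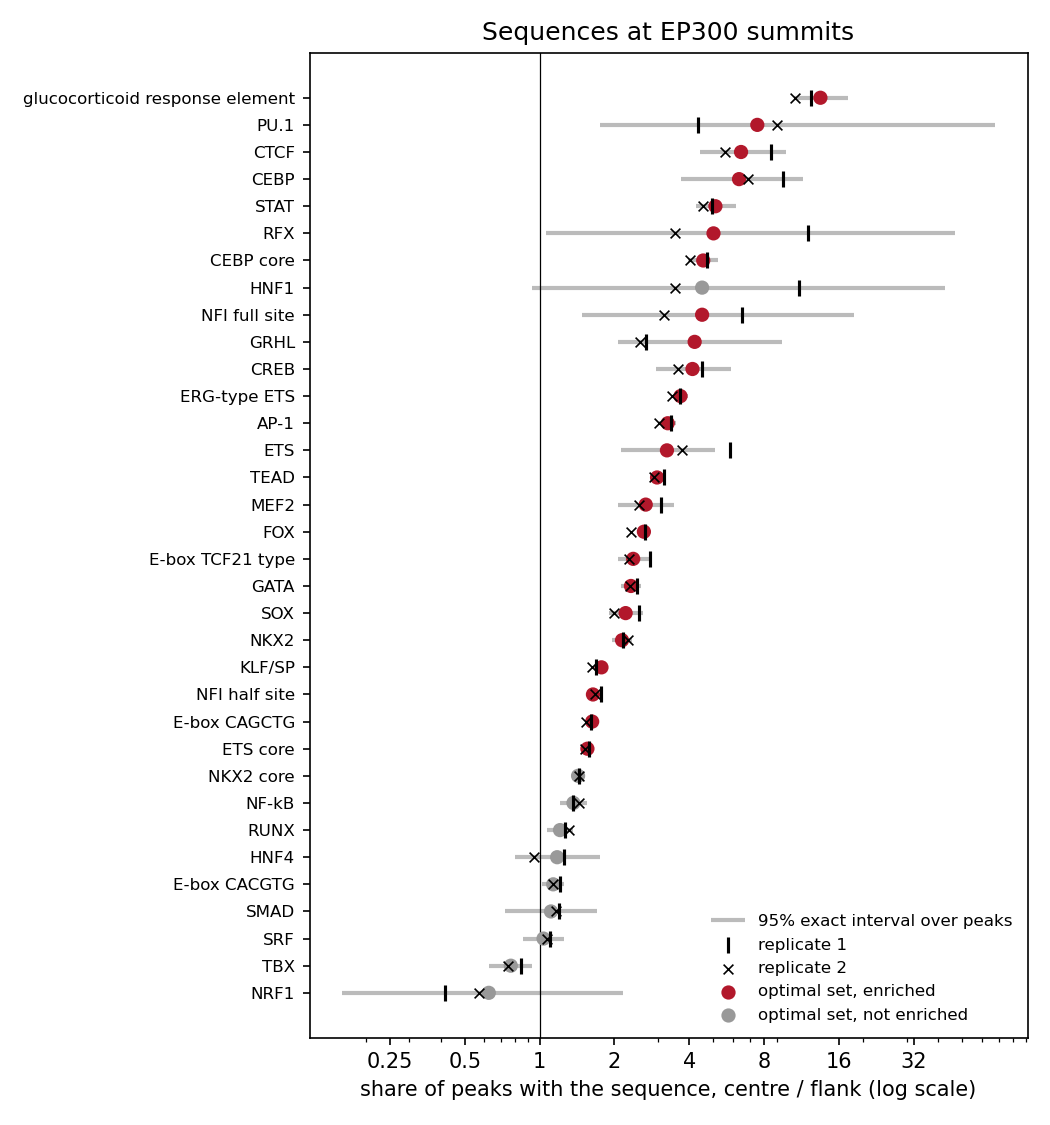
Ratio of the share of EP300 peaks with each consensus sequence in the central 100 bp to that in the flanking window (x axis, log scale) for the 34 sequences with enough matches (rows), with the optimal set as circles (red enriched, grey not), each library alone as black marks and grey bars for the 95% exact interval over peaks. The glucocorticoid response element stood at 13.5, and intervals were widest for PU.1, RFX and HNF1, which had 2 flanking matches each.

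The stitched region with the highest summed EP300 signal and the most peaks surrounded Errfi1. Stitching peaks within a distance just over 12 kb gave 20802 regions, of which 327 held at least 10 peaks and together 10.3% of all peaks. The region with the highest summed signal value (4761) spanned 186 kb on chromosome 4, from 150685156 to 150871573, held 50 peaks and contained the Errfi1 TSS. The second, of 82.8 kb on chromosome 9 (48705558 to 48788332), held 29 peaks inside Zbtb16. The third, on chromosome 17 (31826833 to 31944317), held 36 peaks and the TSS of the kinase gene Sik1. The fourth and the fifth contained TSSs of Stard13 (chromosome 5, 151047034 to 151205318, 40 peaks) and Dlc1 (chromosome 8, 36632004 to 36746559, 34 peaks). Next came Cttnbp2nl (chromosome 3, 104991723 to 105060323, 23 peaks) and the survival gene Bcl2l1 (chromosome 2, 152782628 to 152830935, 24 peaks). The strongest peak of the Bcl2l1 region (signal value 394) was assigned by nearest TSS to Cox4i2, a member of the smooth muscle and pericyte list. The eighth (chromosome 19, 5794784 to 5852410, 33 peaks) had Frmd8 as the nearest protein-coding TSS, 22.9 kb away, and overlapped the long noncoding RNA genes Malat1 and Neat1, which were named after their values were seen. The ninth (chromosome 3, 121577018 to 121679370, 21 peaks) contained the TSS of 4930432M17Rik. The tenth (chromosome 8, 11315821 to 11412165, 34 peaks) lay in Col4a2. Its nearest TSS, 2.99 kb away, was that of the neighbour Col4a1 (11312826), with the TSS of Col4a2 itself (11312805) directly beside it. These are the 2 genes of the main basement membrane collagen.

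No test was attached to this ranking. Of these 10 regions, 9 were among the 10 highest with replicate 1 alone and 7 with replicate 2 alone. The stitching distance mattered more: only 2 overlapped the 10 highest regions with 5 kb and 6 with 25 kb.

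**Figure D4:**
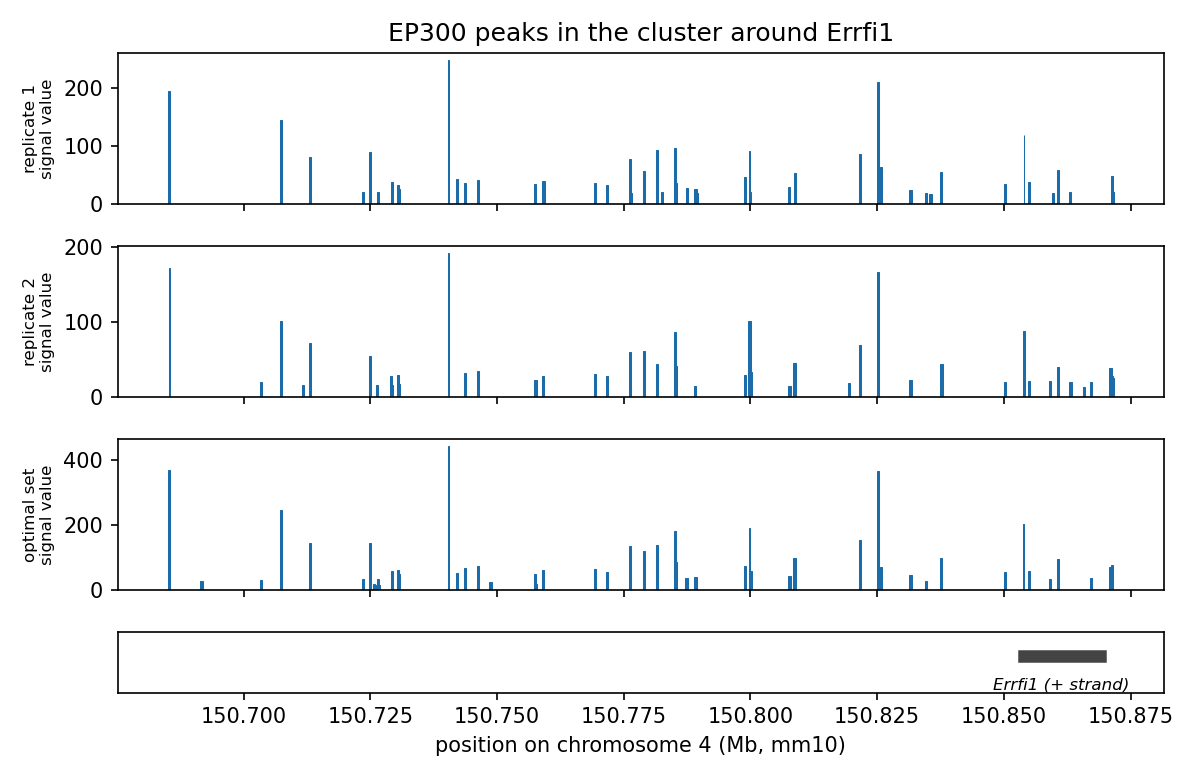
EP300 peaks along the region around Errfi1 on chromosome 4 (x axis, position in Mb on mm10), drawn as bars of the peak's width and signal value (y axis) for the strongest 43988 peaks of each library and for the optimal set, above the extent of the protein-coding gene. The optimal set had 50 peaks in the 186 kb region, most of them upstream of the gene.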

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

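Of the tests below, those of spacing, repeat content and weak promoter peaks had predictions written before they were run, while those of the single libraries, gene density, divided signal and peaks on Y were chosen after the result was seen.

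The optimal set held 16 peaks on sequences other than the 21 chromosomes, which no comparison used. They were singled out because their number was above a fixed floor of 3. Of these, 14 lay on 1 unplaced sequence, with a strongest signal of 117 at rank 4696 of 43988, and that sequence held 44 peaks in replicate 1 and 42 in replicate 2.

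The glucocorticoid response element was most frequent at the strongest distal peaks, in 264 of 3856 of the strongest 10% (ratio to flanks 44). Base composition would have enriched the same paired sites at other spacings too, but the median ratio over the other spacings was 1.5. Repeat copies would have put most summits in masked sequence, but 6.06% of these peaks had theirs there. In the strongest 10% of each library's own distal peaks the lower of both ratios was 32.4 (95% exact interval 16.5 to 68.7), so the pattern did not rest on 1 library. The design had a single group, so no biological explanation was tested.

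The X chromosome held 25.4 pooled peaks per Mb, against 108 to 151 on the autosomes, and 4.13 optimal peaks per Mb against 13.8 to 24.6. Gene density did not account for this, since the lowest of the 5 autosomes of like gene density still had 4.53 times the density of X. Repeat content did not either, since per Mb of unmasked sequence X had 28.8% of the lowest autosome. With autosomal signal values divided by 2, the autosomes had a median of 30.6 peaks per Mb (23.8 to 41.7), a range that holds the value of X, as a single X copy in most cells would give. The Y chromosome, which a male would carry, had 1 pooled peak and 0 optimal peaks, against 156 pooled peaks at the density of X per unmasked Mb. That figure takes the 3.27 unmasked Mb of Y to yield peaks as readily as X does, which was not tested, so it may be too high. The count on Y bears only on a male source of the tissue, not on lower signal on X as such. The explanation by a single X copy stays open, also because sex was not collected and the filtering of reads on Y is not known.

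The weakest 10% of optimal peaks had a promoter share of 17.7%, the highest of any 10%. If weak peaks were kept only beside stronger ones by peak matching, those that overlap none of the strongest pooled peaks should lose the excess, but 17.4% of these 2024 peaks lay in promoters (95% Wilson interval 15.8 to 19.1%). No other explanation, technical or biological, was tested.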

How the results depend on the processing

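Replicate overlap depended on its definition and, more, on the number of peaks taken. From 65.7% it moved to 75.7% with 1 bp of overlap, 71.4% with 50% reciprocal overlap and 52.5% with summits within 50 bp. By number of peaks it was 78.9% for the strongest 1000 peaks, 77.2% for 5000, 63.8% for 50000, 49.5% for 100000 and 29.4% for 300000. Enriched sequences numbered 15 with promoter peaks only, from 24, in a set of 5418 peaks, and 23 to 25 otherwise. Of the 10 highest peak clusters, 2 were kept with a stitching distance of 5 kb and 6 with 25 kb, and 7 to 10 otherwise. The cause of these shifts was not tested. The promoter share stayed between 9.38% and 18.9%, above its background under every alternative, by 1.55-fold (promoters within 2.5 kb) to 5.81-fold (random positions as background). From 11 to 17 gene lists had more peaks, against 13, and 0 to 3 had fewer, against 1. With the stronger 50% of peaks 1 sequence was depleted, against 0. Of 14 list calls, 10 were kept under all 14 alternatives, and of 24 sequence calls, 14 were kept under every alternative that gave a value. Promoter peaks alone had too few matches to give one for PU.1, RFX and the full NFI site, so PU.1, among the 14, was kept under 10 of 11. Of 328 alternative peak counts of 82 named genes, 23 moved by over 1.5 times, at 13 genes, all at Boc, Tead4, Vegfa, Emp2, Ebf1, Neurod1, Camk2a, Apoa1, Cps1, Kcnj2, Rpl28, Actb and Gapdh. No result reversed. Merged peaks, peaks of low pooled rank left out and genes of more than 1 list left out were chosen after seeing the data. Read depth was unknown, so what it limits could not be measured.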

Other observations

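The split of distal peaks by signal, the genes with most peaks and the comparison of low-ranked peaks were chosen after the data had been seen, while the prediction for the response element near glucocorticoid-responsive genes was written before its test was run.

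The sequences at distal peaks varied with signal. From the strongest 10% of distal peaks to the weakest 10%, the TEAD site went from 13.0% to 5.24% of centres, the FOX site from 14.5% to 7.39%, the GATA site from 5.39% to 2.28%, the NKX2 site from 4.93% to 1.76% and the glucocorticoid response element from 6.85% to 0.830%. The site of CTCF, an insulator protein, was in 1 of 3856 centres among the strongest 10% and in 21 of 3855 in the fifth group of 10%. It was in 36 of 3855 in the ninth group and in 16 of 3855 among the weakest. Its share thus mostly rose as signal fell, up to the ninth group, and was lower in the last. These differences were not tested. Over all peaks with the element, its median distance from the summit was 17.5 bp, against 21.75 bp for an even spread.

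Genes with most peaks, whatever their list, were Tns1 with 54, Dlc1 with 53, Nedd9 with 48, Tcf4 with 43 and Stard13 with 41. Tns1 and Nedd9 encode focal adhesion proteins. Of the optimal peaks, 5962 (13.6%) had a pooled rank beyond 43988 and 1519 beyond 100000. Of the latter, 75.2% overlapped one of the strongest 43988 pooled peaks, against 1.42% of other pooled peaks of such rank.

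As a hypothesis, the density of peaks near glucocorticoid-responsive genes could go with direct binding of the receptor, in which case distal peaks assigned to these genes should hold the response element more often than peaks of the same signal elsewhere. Of 234 such peaks, 24 (10.3%) held it, against 8.88 expected, a ratio of 2.70 (permutation test over peaks, p = 4e-05). The 24 lay at 14 of 20 genes, with 4 each at Zbtb16 and Fkbp5. The strongest peak of all, over 100 kb from the Zbtb16 TSS, was not among the 234. The test took peaks as independent, though several lay at the same gene, so its p-value may be too small. The outcome was the one predicted, but a sequence match does not show which protein was bound, so it does not single out this receptor. The nearest gene need not be the target, and receptor binding was not measured here.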
